A study of Homo sapiens with 12 samples.

How the data were processed

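The series holds 12 Illumina bead arrays of RNA from HEK293T cells transfected with biotinylated duplexes of 2 microRNAs, miR-3118-3p and miR-4307-3p. The labels give 3 pull-down and 3 input arrays per microRNA, and groups and replicate numbers were taken from the sample titles. The log2 values used here are those of the deposited series matrix, made by the authors with lumi 2.2.1, per the submitters' processing notes. The normalization method, the choice between a plain log2 and a variance-stabilising transform, and the filter that chose the 15025 probes are not given in the sources used here. Quartiles were nearly equal on all arrays (medians from 7.53 to 7.59), as after a normalization between arrays. No pair of arrays held identical values (0 pairs). Signal over background could not be read from these values, so no detection filter was applied. RNA was labelled with biotin after amplification for hybridization, per the labels' protocols, in pull-downs and inputs alike.

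A separate table of signals before normalization has 12 value columns whose names match no sample label. They were not used, because a column may not be matched by order or by its values. Background correction with neqc and a filter on detection had been planned on that table; the plan named the series matrix as the fallback, and it was followed. The criterion of detection in the rule for named genes fell away for the same reason. A planned comparison of genes with and without seed sites was not run, since no transcript sequences were used here, and no coordinates are given because no genome build is named.

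Gene names came from the platform annotation, updated through gene identifiers. Of 15025 probes, 12354 had 1 symbol, 2 had several and 2669 were not listed in the annotation used; 12352 were named through the identifier, and 2 symbols were updated. Probes with several or no symbols were kept out of the gene tests. For 2331 genes with several probes, the probe with the highest mean over the 12 arrays was taken, which left 9581 genes. Among called genes with several probes, all probes went the same way for 541 of 652 with miR-3118-3p, 377 of 409 with miR-4307-3p and 211 of 221 for the difference between the microRNAs.

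The model was fitted with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, with lmFit and eBayes over 4 group means and all 12 arrays, so that the groups shared 1 estimate of the spread with 8 residual degrees of freedom. The 4 comparisons were each pull-down against its input, the difference of the enrichments and input against input. P-values were two-sided and adjusted by Benjamini-Hochberg over the 9581 genes of each comparison, with a threshold of 0.05. Intervals are 95%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Before the data were examined, 31 gene lists were fixed, covering metabolism, translation, RNA processing, signalling, cell cycle, stress and cell type markers. The 28 with at least 5 measured genes were tested by camera with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the 28 lists; blood, epithelial and renal, and hepatocyte markers had too few measured members, 3, 3 and 1.

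Named genes followed a rule fixed before the data were examined. For each pull-down against input it takes the 12 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap. For the other comparisons it takes the 5 largest in each direction. It adds up to 4 members of each list described, every member of lists of at most 10 genes, and ACTB and GAPDH. X-inactivation and Y-linked transcripts were left out. Probes without a gene name were tested in the same way, apart from the genes.

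The fit was tested on simulated data, with 200 of 9581 genes changed. Values were drawn independently from normal distributions with 1 SD per gene, pooled over the 4 groups. Of genes changed by 0.5, 1 and 2 on the log2 scale it called 38.8%, 89.6% and 100% for miR-3118-3p, 28.4%, 85.1% and 100% for miR-4307-3p, and 1.49%, 74.6% and 95.5% for the difference of enrichments. Unchanged genes called numbered 9, 9 and 3. The wider spread of the miR-3118-3p pull-down (median SD 0.230, against 0.128 to 0.135 in the other groups) was not simulated. The shares and false calls for that pull-down may therefore be too favourable. Settings were alike for the 2 microRNAs, so the gap between their shares came from random draws.

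Replicate numbers come from the titles. Deviations from the group means of same-numbered pull-down and input arrays correlated across all probes at 0.204, 0.342 and 0.286 for miR-4307-3p, all over 0.1, so the numbers were taken to pair those arrays. The main fit has no block, as planned, so it leaves this pairing out. The fit with the replicate number as a block is an alternative. That block joins same-numbered arrays of both microRNAs, and a block within each microRNA was not run. Other alternatives counted every probe, averaged probes, used eBayes with trend and robust, array weights, only the arrays of the contrast, a minimum difference of 1, the pull-downs set directly against each other, or left out each array in turn. Quantile normalization, cyclic loess and median scaling of the deposited values, a minimum mean of 7, and for gene lists the block with an estimated correlation were added after seeing the data.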

Results

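RNA was measured in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. The cells had received 200 pmol of a synthetic microRNA duplex that carried biotin, miR-3118-3p in one set of cells and miR-4307-3p in the other. Cells were harvested 24 hours later, and the microRNA with the RNA bound to it was recovered on streptavidin beads, which bind biotin. An input sample was measured beside each pull-down. The 12 Illumina bead arrays form 4 groups of 3, pull-down and input for each of the 2 microRNAs, and the small number of arrays limits the precision of every value. The deposited values lie on a log2 scale, with medians between 7.53 and 7.59 per array, and differences are given on that scale with the standard error (SE) of the fit and n = 3 arrays per group. Pull-downs and inputs had nearly equal medians, so higher, lower, enriched and depleted are relative to the other RNA on the arrays. Absolute recovery is unknown, and a near balance of higher and lower genes may follow from this scaling. Whether the scale is plain log2 or variance-stabilised is not given in the sources used here, so a difference of 1 may not be an exact doubling for dim probes. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

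The table covers 9581 named genes. It appears to have been selected on the input level, because no input value lay under 5.69 while 95 probes in the miR-3118-3p pull-down and 96 in the miR-4307-3p pull-down had a mean under the lowest input value. RNA present in a pull-down alone could therefore have been left out of the table. Within groups, arrays correlated across all probes, which are not independent replicates, at 0.988 or more in the inputs and the miR-4307-3p pull-down. In the miR-3118-3p pull-down, replicate 1 stood apart, with correlations of 0.963 and 0.968 to the others. The median SD over genes was 0.230 in that group and between 0.128 and 0.135 in the other groups.

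The first comparison asked which RNAs were recovered with miR-3118-3p, by setting its pull-down against its input. The most enriched mRNA among named genes was ACACA, which encodes acetyl-CoA carboxylase 1, the rate-limiting enzyme of fatty acid synthesis, at 3.31 ± 0.17 (SE, n = 3 per group; adjusted p = 2.67e-08). PRKDC, the catalytic subunit of DNA-dependent protein kinase, rose by 1.96 ± 0.25, and MIER1, a transcriptional repressor, by 1.89 ± 0.20. MRPS18B, a mitochondrial ribosomal protein, rose by 1.75 ± 0.16, and NUP160, a nuclear pore protein, by 1.71 ± 0.17. The mRNAs of MDN1 (a ribosome assembly ATPase, 1.71 ± 0.26), ZMPSTE24 (the prelamin A protease, 1.71 ± 0.19), AMOT (angiomotin, 1.69 ± 0.32), ATG12 (an autophagy conjugation protein, 1.65 ± 0.22), HERC2 (a giant ubiquitin ligase, 1.65 ± 0.33), KLHL23 (1.62 ± 0.22) and PLCXD1 (1.58 ± 0.20) followed. For each of these 12 genes, all 3 pull-down values lay above all 3 input values, which the rule for named genes required.

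The RNAs most depleted from the miR-3118-3p pull-down included mRNAs of ribosomal proteins and of an ATP synthase subunit. RPL36A changed by -1.44 ± 0.18, RPL29 by -1.36 ± 0.18 and RPS7 by -1.17 ± 0.17, although processed pseudogenes of ribosomal protein genes make the source of such probes uncertain. ATP5F1E, the epsilon subunit of ATP synthase, changed by -1.40 ± 0.20. ATG4B (an autophagy protease, -1.19 ± 0.26), PSMC4 (a proteasome ATPase, -1.17 ± 0.28) and MCTS1 (a translation reinitiation factor, -1.15 ± 0.17) were also lower. ATG4B and PSMC4 were less certain: over 22 other settings they ranged from -1.51 to -0.79 and from -1.49 to -0.72, nearest to 0 with array weights, where PSMC4 was not called (adjusted p = 0.0503). RFC2, a subunit of the clamp loader of DNA replication, was lower by its brighter probe, at -1.26 ± 0.18, while its other probe gave -0.09.

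Across the table, 1216 genes (12.7%) were higher and 1042 (10.9%) lower in the miR-3118-3p pull-down than in its input (limma, adjusted p under 0.05). Of these, 157 and 29 differed by at least 1. The 3 values of each group did not overlap for 34.8% of genes, where chance gives 10%. The spread shared by the groups draws on groups with a smaller SD than this pull-down. Standard errors and p-values may therefore be too small here. With the spread taken from these 6 arrays alone, the counts were 575 higher and 409 lower, and with median scaling 1102 and 1167. The count of lower genes was 652 without pull-down replicate 2, and 624 and 669 without input replicates 2 and 3 of miR-3118-3p.

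Of 72 measured genes of nuclear-encoded oxidative phosphorylation, 33 were lower and 6 higher (40 and 8 adjusted over the list alone), including NDUFA3 of complex I at -1.08 ± 0.12, COX5B of complex IV at -0.85 ± 0.11 and ATP5PO of ATP synthase at -0.76 ± 0.12; camera gave adjusted p = 1.23e-07 for the list, and adjusted p = 0.0645 with an estimated correlation. Of 74 mitochondrial ribosomal proteins, 35 were lower and 3 higher (37 and 3 adjusted over the list alone), with MRPL40 at -1.06 ± 0.16 and MRPS18C at -0.99 ± 0.13, against the higher MRPS18B. That list had adjusted p = 1.43e-07, and adjusted p = 0.225 with an estimated correlation. Among 68 cytosolic ribosomal proteins 18 were lower and 5 higher (19 and 6 adjusted over the list alone), with RPS26 at -0.83 ± 0.14; the list had adjusted p = 0.0269, and adjusted p = 0.365 with an estimated correlation. Among 39 proteasome genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone), at adjusted p = 0.0269, and adjusted p = 0.740 with an estimated correlation. The call of the cytosolic ribosomal list was lost in 5 of 19 other settings, among them those without pull-down replicate 2 (adjusted p = 0.104) and without input replicate 1 (0.0586) of miR-3118-3p. That of the proteasome list was lost in 7 of 19, among them quantile normalization (0.0557), cyclic loess (0.158) and those without pull-down replicates 1 (0.0753) and 2 (0.104) or input replicate 3 (0.128).

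Replication-dependent histone mRNAs, which end in a stem-loop in place of a poly(A) tail, were lower for 6 of 17 measured genes and higher for 0 (9 and 0 adjusted over the list alone). H2AC25 stood at -1.05 ± 0.14 and H4C3 at -0.74 ± 0.12, and the list had adjusted p = 2.06e-05, and adjusted p = 0.320 with an estimated correlation; near-identical histone copies make the source of these probes uncertain. Of 20 nuclear-retained or snoRNA-host noncoding RNAs, 8 were lower and 2 higher (12 and 2 adjusted over the list alone), with SNHG6 at -0.75 ± 0.14 and SNHG5 at -0.71 ± 0.15. This list had adjusted p = 0.00179, and adjusted p = 0.320 with an estimated correlation.

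Of 50 E3 ubiquitin ligases and adaptors, 20 were higher and 0 lower (21 and 0 adjusted over the list alone), with KLHL42 at 0.95 ± 0.15 and NEDD4L at 0.68 ± 0.12 beside HERC2; the list had adjusted p = 1.33e-05, and adjusted p = 0.309 with an estimated correlation. Of 139 KRAB zinc finger genes, a large family of transcriptional repressors, 36 were higher and 6 lower (40 and 7 adjusted over the list alone), with ZNF562 at 1.31 ± 0.20 and ZNF573 at 1.15 ± 0.17. That list had adjusted p = 0.00622, and adjusted p = 0.413 with an estimated correlation. In the list of microRNA processing and silencing genes, 7 of 17 were higher and 0 lower (7 and 0 adjusted over the list alone), among them TNRC6A at 1.10 ± 0.15 and TNRC6B at 0.74 ± 0.18, which encode scaffold partners of Argonaute, and IPO8 at 0.91 ± 0.14. It had adjusted p = 0.00170, and adjusted p = 0.0645 with an estimated correlation. For TGF-beta, Wnt and Notch signalling 11 of 48 genes were higher and 1 lower (11 and 1 adjusted over the list alone), with TCF4 at 1.01 ± 0.16 and the receptor BMPR2 at 0.97 ± 0.17, at adjusted p = 0.0491, and adjusted p = 0.342 with an estimated correlation; the call of this list was lost in 15 of 19 other settings, most of which left out 1 array.

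The second comparison asked the same of miR-4307-3p. LARP7, a protein that stabilises the 7SK noncoding RNA, was the most enriched mRNA among named genes, at 3.54 ± 0.16 (SE, n = 3 per group; adjusted p = 2.30e-09), and both of its probes rose, the other by 3.82. ACACA came next at 3.14 ± 0.17 (adjusted p = 2.14e-08). BEX5 rose by 3.05 ± 0.17, HMGN5, a nucleosome-binding protein, by 2.73 ± 0.23, and ERICH5, named for its glutamate-rich sequence, by 2.65 ± 0.15. CCDC112, a coiled-coil domain protein, rose by 2.55 ± 0.15, and C16orf87 by 2.35 ± 0.21. Values of 2.30 were found for NSRP1, a splicing regulator (SE 0.13), NOP58, a core protein of box C/D snoRNPs (SE 0.20), and GNL2, a nucleolar GTPase of ribosome assembly (SE 0.18). IFT74, a protein of intraflagellar transport, and the small GTPase RAB13 rose by 2.25 ± 0.15 and 2.18 ± 0.16. All 3 pull-down values of these 12 genes lay above all 3 input values, again as the rule required.

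Among the most depleted RNAs of the miR-4307-3p pull-down, GNG10, a G protein gamma subunit, changed by -1.35 ± 0.19, the snoRNA host transcript SNHG17 by -1.14 ± 0.17, and RPS7 by -1.13 ± 0.17. HSPA6, a stress-inducible chaperone (-1.09 ± 0.23), BPHL, a serine hydrolase (-1.07 ± 0.13), and RBM4, a splicing factor (-0.97 ± 0.18), were also lower. The noncoding RNA SNAR-A1 (-1.06 ± 0.16) and the pseudogene PTTG3P (-0.99 ± 0.14) were lower too, although both have near-identical copies and their probes are uncertain.

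In total 770 genes (8.04%) were higher and 585 (6.11%) lower in the miR-4307-3p pull-down than in its input, 211 and 6 of them by at least 1. The values of the groups did not overlap for 39.1% of genes, where chance gives 10%. The shared spread takes in the wider miR-3118-3p pull-down, so p-values may be too large here. With the spread taken from these 6 arrays alone the counts were 1266 and 1183, above the 575 and 409 of miR-3118-3p in that setting. Which microRNA had more called genes against its input thus depended on the setting. Array weights gave 1593 higher and 1619 lower, so that the lower genes were then the more numerous, and cyclic loess gave 898 and 378. The count of lower genes was 964 without replicate 1 of the miR-3118-3p pull-down, which enters through the shared spread; it was 290 and 234 without pull-down replicates 2 and 3 of miR-4307-3p, and 318, 275 and 331 without its input replicates 1, 2 and 3.

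Of the 72 oxidative phosphorylation genes, 35 were lower and 2 higher with miR-4307-3p (39 and 2 adjusted over the list alone). COX5B stood at -0.78 ± 0.11, ATP5PO at -0.78 ± 0.12 and NDUFA3 at -0.65 ± 0.12, while ATP5ME, another ATP synthase subunit, rose by 0.92 ± 0.11. The list had adjusted p = 1.20e-10, and adjusted p = 0.0284 with an estimated correlation, the only list still called with it. That call was lost when the replicate number was a block as well (adjusted p = 0.148). Mitochondrial ribosomal proteins went both ways, with 18 of 74 lower and 10 higher (23 and 11 adjusted over the list alone). MRPL50 stood at -0.86 ± 0.14, against rises of 1.67 ± 0.16 for MRPS23 and 1.61 ± 0.13 for MRPL52; the list had adjusted p = 0.0252, and adjusted p = 0.623 with an estimated correlation. Of 68 cytosolic ribosomal proteins 13 were lower and 1 higher (16 and 1 adjusted over the list alone), the exception being RPL26 at 1.20 ± 0.18. This list had adjusted p = 0.00865, and adjusted p = 0.418 with an estimated correlation. With cyclic loess the call of the mitochondrial ribosomal list (adjusted p = 0.0812) and that of the cytosolic one (0.0829) were lost, and the first also without pull-down replicate 3 (0.0563).

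Of the 17 histone mRNAs, 4 were lower and 0 higher (10 and 0 adjusted over the list alone), with H2AC25 at -0.97 ± 0.14 and H4C3 at -0.71 ± 0.12; the list had adjusted p = 0.000102, and adjusted p = 0.418 with an estimated correlation. Noncoding RNAs included 3 lower and 1 higher of 20 (5 and 2 adjusted over the list alone), with the snoRNA host ZFAS1 at -0.78 ± 0.13, at adjusted p = 0.0382, and adjusted p = 0.623 with an estimated correlation. Glycolysis included 2 lower and 0 higher of 21 genes (2 and 0 adjusted over the list alone), GPI at -0.65 ± 0.13 and PGAM1 at -0.69 ± 0.15, at adjusted p = 0.0255, and adjusted p = 0.742 with an estimated correlation. Of 81 chromatin regulators, 13 were higher and 0 lower (13 and 0 adjusted over the list alone). Among these were the heterochromatin proteins CBX3 (1.63 ± 0.23, its dimmer probe 0.43) and CBX1 (0.99 ± 0.18) and the remodeller CHD2 (1.09 ± 0.15), and the list had adjusted p = 0.00172, and adjusted p = 0.418 with an estimated correlation. Of 50 E3 ligases and adaptors 5 were higher and 0 lower (4 and 0 adjusted over the list alone), with UBE3A at 1.94 ± 0.18 and HERC2 at 1.60 ± 0.33. That list had adjusted p = 0.0252, and adjusted p = 0.623 with an estimated correlation. MicroRNA pathway genes had 4 of 17 higher and 0 lower (6 and 0 adjusted over the list alone), including LIN28B, an inhibitor of let-7 processing, at 0.83 ± 0.19, at adjusted p = 0.0218, and adjusted p = 0.202 with an estimated correlation. The call of the noncoding list was lost in 8 of 19 other settings, among them those without pull-down replicates 2 (adjusted p = 0.0992) and 3 (0.0527) or input replicate 3 (0.0809) of miR-4307-3p. That of glycolysis was lost in 6 of 19, among them those without input replicate 2 (0.115) and pull-down replicate 3 (0.0527), and that of E3 ligases without pull-down replicate 3 (0.0563).

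**Figure D1:**
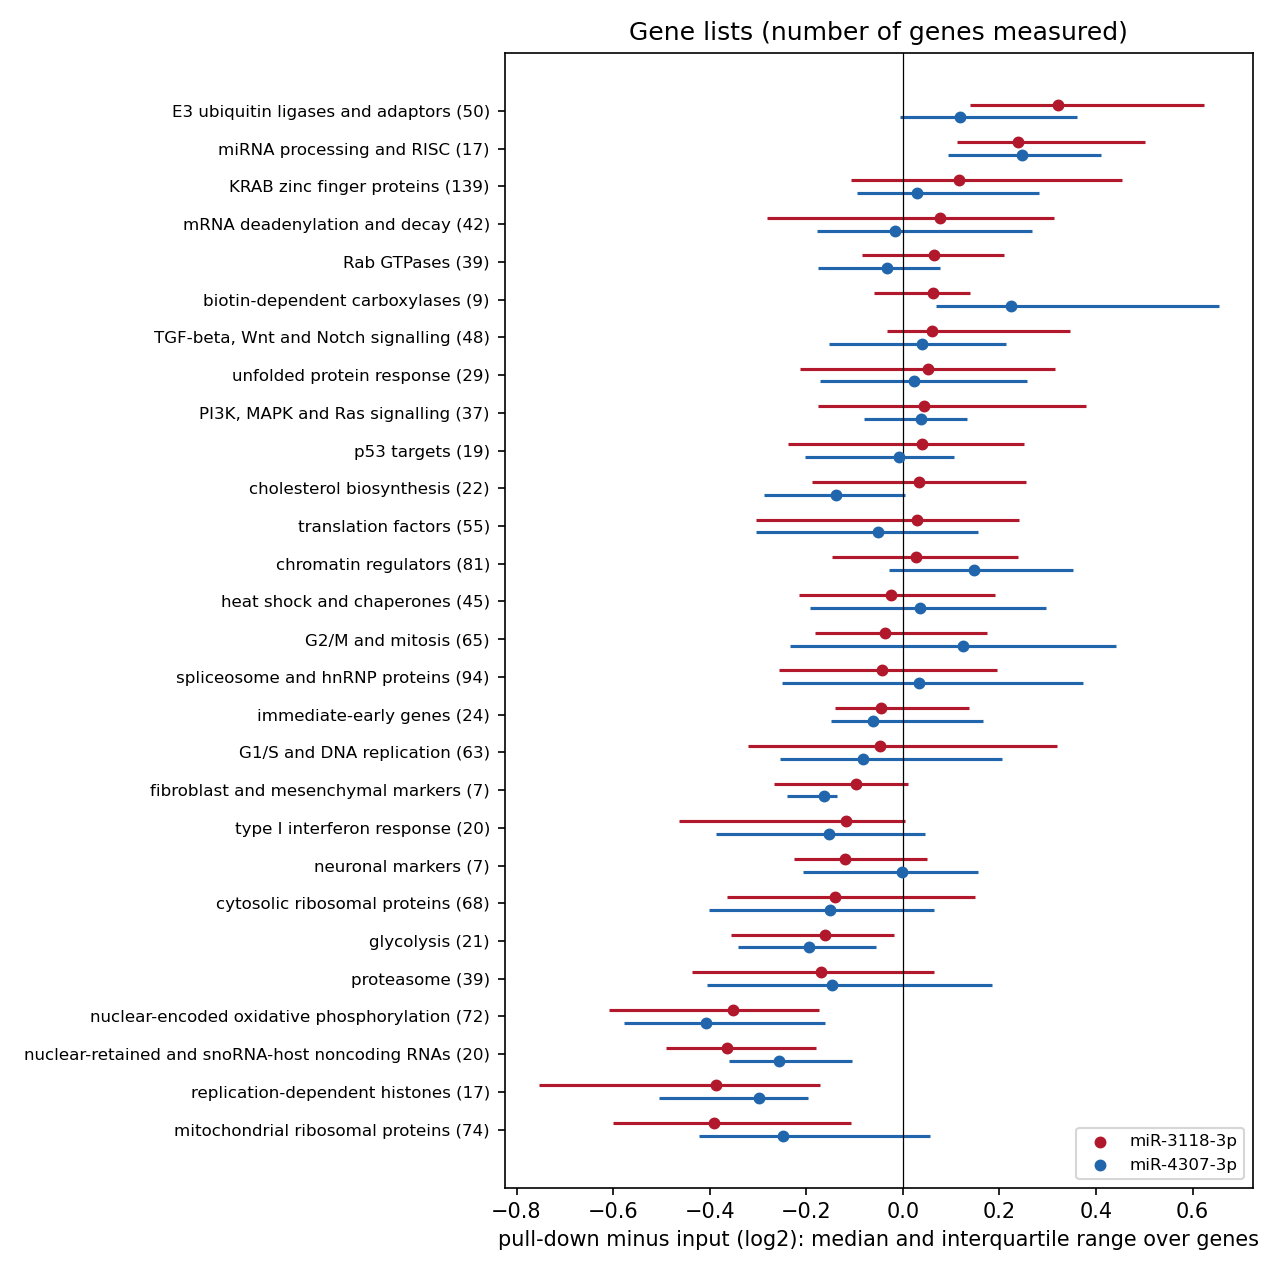
Medians (points) and interquartile ranges (lines) over genes of pull-down minus input on the log2 scale, for the 28 lists with at least 5 measured genes, with miR-3118-3p in red and miR-4307-3p in blue. Oxidative phosphorylation has medians of -0.35 and -0.41.

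Carboxylases that carry biotin are a known background of streptavidin beads. The list of 9 genes holds those that carry it (ACACA, ACACB, PC, PCCA and MCCC1), the partner subunits PCCB and MCCC2, the biotin ligase HLCS and the biotinidase BTD. ACACA and its paralogue ACACB rose with both microRNAs, ACACB by 0.98 ± 0.14 with miR-3118-3p and by 0.95 ± 0.14 with miR-4307-3p. With miR-3118-3p the other 7 did not pass the test, at 0.06 for PC, -0.01 for PCCA, -0.40 for PCCB, -0.06 for MCCC1, -0.25 for MCCC2, 0.14 for HLCS and 0.13 for BTD (2 higher and 0 lower adjusted over the list alone). With miR-4307-3p, MCCC1 was at 0.65 ± 0.16 (adjusted p = 0.0134) and MCCC2 at -0.40 ± 0.12 (adjusted p = 0.0363). Over the other settings the adjusted p reached 0.0766 for MCCC1, past the threshold in 3 of 22, and 0.160 for MCCC2, past it in 9 of 21, most of them settings that left out 1 array. PC (0.24), PCCA (0.08), PCCB (-0.50), HLCS (0.22) and BTD (0.07) did not pass (3 higher and 2 lower adjusted over the list alone). PCCB was called lower in 3 of 22 other settings with miR-4307-3p: array weights (adjusted p = 0.00142), the spread of those 6 arrays alone (0.00753) and without miR-3118-3p pull-down replicate 1 (0.0124). With miR-3118-3p it was called lower without pull-down replicate 3 (0.0390). As a list they were not called in either comparison (adjusted p = 0.307 and 0.0563), except with the replicate number as a block for miR-4307-3p (adjusted p = 0.0388, and adjusted p = 0.623 with an estimated correlation).

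**Figure D2:**
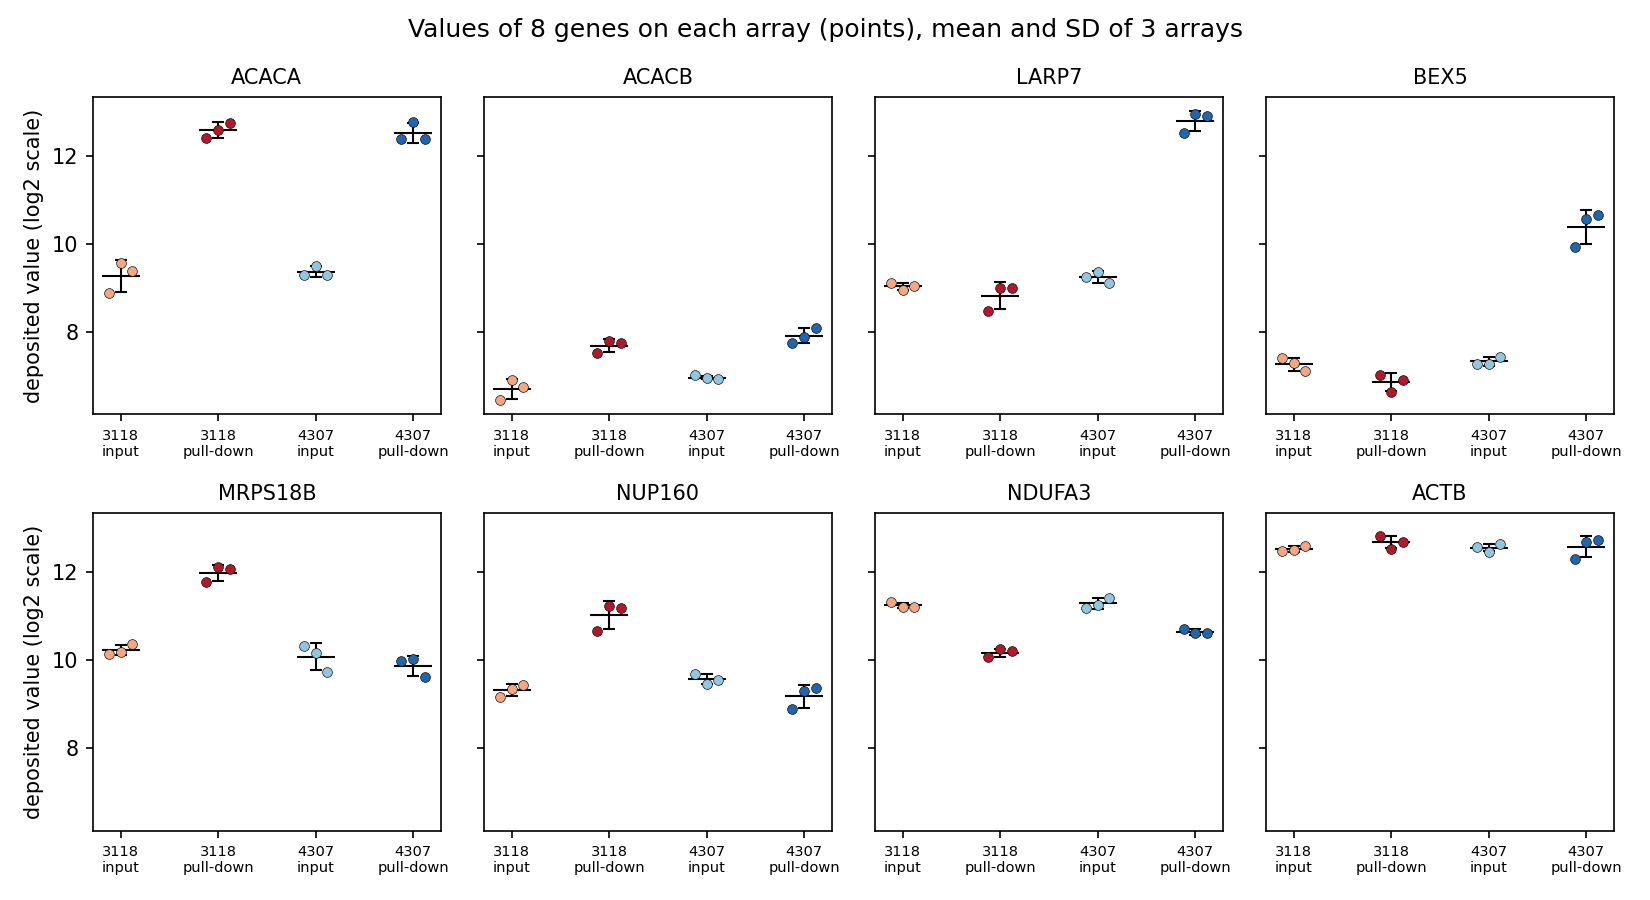
Deposited values on the log2 scale of 8 genes on each of the 12 arrays (points), with the mean and SD of the 3 arrays of each group. ACACA is high in both pull-downs, LARP7 in that of miR-4307-3p alone and NUP160 in that of miR-3118-3p alone, and ACTB was called in neither comparison.

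The reference transcripts ACTB and GAPDH did not pass the test in either comparison. ACTB was at 0.16 ± 0.14 with miR-3118-3p and 0.01 ± 0.14 with miR-4307-3p, and GAPDH at -0.28 ± 0.14 and -0.36 ± 0.14. Their probes disagreed, since another ACTB probe gave -0.80 with miR-4307-3p (adjusted p = 0.0286 over all probes). GAPDH passed the test in both comparisons without replicate 1 of the miR-3118-3p pull-down, at -0.41 (adjusted p = 0.0242) and -0.36 (adjusted p = 0.0389). With miR-4307-3p it also passed with array weights (adjusted p = 0.0143) and with the spread of those 6 arrays alone (adjusted p = 0.0325).

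The third comparison tested whether enrichment differed between the microRNAs. LARP7 (-3.76 ± 0.22), BEX5 (-3.46 ± 0.24), HMGN5 (-3.21 ± 0.32), ERICH5 (-2.91 ± 0.22) and COMMD6 (-2.65 ± 0.20) had the largest excess with miR-4307-3p, as miR-3118-3p minus miR-4307-3p enrichment. In the other direction NUP160 (2.09 ± 0.23), MRPS18B (1.96 ± 0.23), SH3BGRL (1.84 ± 0.30), COMMD9 (1.78 ± 0.25) and KLHL23 (1.69 ± 0.31) were more enriched with miR-3118-3p. In all, 274 genes were more enriched with miR-3118-3p and 453 with miR-4307-3p, with 94 and 264 of them differing by at least 1. Of these genes, 230 were also higher in the miR-3118-3p pull-down than in its input, and 374 higher in the miR-4307-3p pull-down than in its input. Which microRNA had more genes depended on the setting: without replicate 1 of the miR-3118-3p pull-down 754 were in favour of miR-3118-3p and 592 of miR-4307-3p, and with array weights 660 and 623. With the pull-downs set directly against each other the counts were 929 and 945. The count in favour of miR-3118-3p was 168 without its input replicate 2, 182 without miR-4307-3p pull-down replicate 3, and 178 and 175 without miR-4307-3p input replicates 2 and 3.

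No difference between the microRNAs was called for ACACA, at 0.16 with a 95% interval from -0.36 to 0.68, or for ACACB, at 0.03 with an interval from -0.39 to 0.45. ACTB (0.14) and GAPDH (0.08) were not called either. MCCC1 was at -0.71 (adjusted p = 0.0769), and was called in 4 of 22 other settings: with the replicate number as a block (adjusted p = 0.0234), without miR-4307-3p input replicate 2 (0.0395), without miR-3118-3p pull-down replicate 3 (0.0460) and with the pull-downs set directly against each other (0.00307). None of the 28 lists was called for the difference, 0 with the preset and 0 with an estimated correlation. When single arrays were left out, 0 to 2 lists were called with the preset correlation. Mitochondrial ribosomal proteins came closest in the main fit, at adjusted p = 0.0516, with 12 of 74 members more enriched with miR-4307-3p and 2 with miR-3118-3p (14 and 3 adjusted over the list alone). With the replicate number as a block this list was called (adjusted p = 0.0451, and adjusted p = 0.947 with an estimated correlation). The block also joins same-numbered arrays of the 2 microRNAs, which were not shown to pair.

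**Figure D3:**
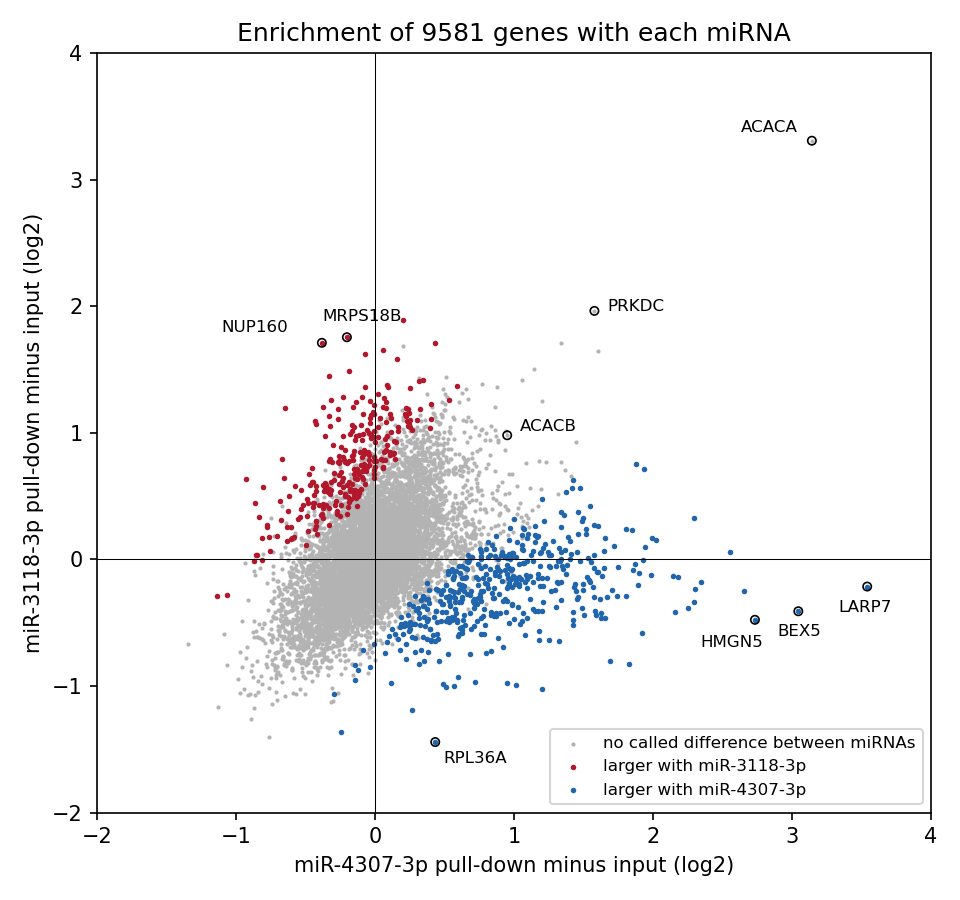
Pull-down minus input on the log2 scale for 9581 genes with miR-4307-3p (horizontal) and miR-3118-3p (vertical), each point a gene. Red marks the 274 genes more enriched with miR-3118-3p and blue the 453 more enriched with miR-4307-3p; ACACA lies high on both axes.

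The differences from input share no arrays, but the calls are not independent, since the spread of each gene was estimated from all 12 arrays. A gene with a small spread is thus more readily called in both comparisons, and the numbers for independent lists leave this out. Both comparisons called 157 genes higher, where independent lists of these sizes would share 97.7, and 308 genes lower, where independent lists would share 63.6. Genes higher with miR-3118-3p and lower with miR-4307-3p numbered 13 against 74.2, and the reverse 69 against 83.7. Across genes, which are not independent replicates, the enrichments correlated with Pearson's r of 0.351 and Spearman's rho of 0.444.

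The inputs were compared with each other to see whether cells given one microRNA differed in total RNA from cells given the other. No gene passed the test (0 by limma), and the values did not overlap for 9.23% of genes, where chance gives 10%. An unadjusted p under 0.05 was found for 160 of 9581 genes, fewer than the share of 0.05 that chance gives. The shared spread takes in the wider miR-3118-3p pull-down, which may make this test too strict. With the spread of the input arrays alone, 0 genes were called as well. ACTB was at -0.04 ± 0.14 and GAPDH at 0.01 ± 0.14. In simulated data with 1 spread per gene, pooled over the 4 groups, 91.0% of genes changed by 1 and 19.4% of genes changed by 0.5 were called. Smaller changes were not simulated. The list of mRNA deadenylation and decay was lower in the miR-3118-3p input (median -0.09, adjusted p = 0.0115) with 0 of its 42 members called, 0 adjusted over the list alone, and adjusted p = 0.0846 with an estimated correlation. Its call was lost in 7 of 19 other settings, among them those without input replicates 2 (adjusted p = 0.0940) and 3 (0.170) of miR-3118-3p and 1 (0.0534) and 3 (0.0680) of miR-4307-3p.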

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

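The tests of the input difference, of probes and of the ACACA difference were chosen after their results were seen; the 3 added gene lists (very large proteins, ribosome biogenesis factors and CCDC genes) were prompted by the leading genes, which were left out of them, and all 3 are reported. Requiring the estimated correlation as well for an added list was decided after its p-values were seen, as was requiring PC, PCCA and MCCC1 to rise for the biotin explanation; both made the reading stricter.

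Enrichment differed between the microRNAs by a test of the difference itself, for 274 genes in favour of miR-3118-3p and 453 in favour of miR-4307-3p. The named genes were NUP160 (2.09), MRPS18B (1.96), SH3BGRL (1.84), COMMD9 (1.78) and KLHL23 (1.69) on one side, and LARP7 (-3.76), BEX5 (-3.46), HMGN5 (-3.21), ERICH5 (-2.91) and COMMD6 (-2.65) on the other. Of 100 splits of the pull-downs and inputs, the real one included, 11 gave as many of these genes, so chance is not excluded by that count. The real count was 727 and the highest other 1025. The 11 other splits that kept the pull-downs as labelled regrouped only the inputs, in which no gene was called. Splits that mixed the pull-downs gave at most 0 genes. Mixing puts the difference between the pull-downs into the spread, so few calls there were likely in advance. For gene lists, 100 of 100 splits gave as many calls, with 0 for the real split and 9 for the highest other. Any split gives at least 0, so that share was fixed in advance and tests nothing.

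The 374 genes that were higher with miR-4307-3p, and more so than with miR-3118-3p, had a median difference of -1.15. A difference between the inputs is argued against, since the median input difference accounted for 1.26% of it. Single probes reading other transcripts are argued against as well, since all probes went the same way for 95.8% (92 of 96) of these genes that have several. Among the leading genes, CCDC112, NSRP1 and IFT74 encode coiled-coil proteins, and the 49 other measured genes named CCDC had a median difference of -0.26, with 11 more enriched with miR-4307-3p and 0 with miR-3118-3p (camera p = 2.90e-06, and p = 0.000460 with an estimated correlation); their medians were 0.09 with miR-4307-3p (14 higher and 0 lower) and -0.07 with miR-3118-3p (5 higher and 10 lower), so part of the difference may come from lower values with miR-3118-3p. For the rise with miR-4307-3p a candidate explanation is pairing of miR-4307-3p with coding sequence that such proteins share, a hypothesis that stays open because no transcript sequences were searched; ribosome biogenesis factors gave p = 0.00825, and p = 0.420 with an estimated correlation, which does not settle it.

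ACACA and ACACB were recovered with both microRNAs. General recovery of very long mRNAs is argued against as the cause for ACACA, since the upper quartile of 86 other very large proteins was at most 0.46. That list rests on protein size and not on measured mRNA length. It also leaves out PRKDC, MDN1, HERC2 and UBR4, which had prompted it, among them PRKDC at 1.96 with miR-3118-3p. A probe reading another transcript is argued against too, as the lowest value of either ACACA probe was 3.14. Biotin on the nascent carboxylase, held to its mRNA by the ribosome and bound by the beads, is a candidate explanation that stays open. The ACACA difference of 0.16 between the microRNAs restates that ACACA rose with both. The other carboxylases that carry biotin did not rise with miR-3118-3p (PC 0.06, PCCA -0.01, MCCC1 -0.06) nor, for PC (0.24) and PCCA (0.08), with miR-4307-3p. MCCC1 was called higher with miR-4307-3p, though not in every setting. The condition that PC, PCCA and MCCC1 all rise with both microRNAs was therefore not met. Whether those proteins carry biotin while still on the ribosome was not measured, so the unmet condition does not settle the biotin explanation. Shared targeting by both microRNAs stays open too, since no pull-down without a microRNA was analysed here.

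Probes without a gene name also carried signal. Of 2671 such probes, 279 were higher and 486 lower in the miR-3118-3p pull-down than in its input, and 196 and 312 in that of miR-4307-3p. The largest rise, for ILMN_3229570 with miR-4307-3p, was 3.94, and the largest fall, for ILMN_1743078 with miR-3118-3p, was -1.82.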

How the results depend on the processing

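Quantile, loess and median scaling, the minimum mean of 7, and the estimated correlation with the replicate number as a block, were added after seeing the data. Settings on the signal table (neqc, background correction, detection filters) and for seed sites were not run. Signal over background is unknown, so dim probes limit small differences.

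Counts of genes moved as follows, and except where said the cause was not tested. Counting every probe gave 1928 lower with miR-3118-3p, 1181 higher and 1247 lower with miR-4307-3p, and 416 and 724 for the difference, over more items. Array weights gave 1593 and 1619 with miR-4307-3p and 660 higher for the difference, against 623 lower. Only the groups of the contrast gave 575 and 409 with miR-3118-3p and 1266 and 1183 with miR-4307-3p; the first group has the wider spread. A minimum of 1 gave, by construction, 157 and 29, 211 and 6, and 94 and 264. Cyclic loess gave 378 lower with miR-4307-3p, and the pull-downs set against each other 929 and 945. Leaving out single arrays gave 812 to 1696 higher and 624 to 1453 lower with miR-3118-3p, 519 to 1051 and 234 to 964 with miR-4307-3p, and 168 to 754 and 355 to 592 for the difference. Higher and lower genes changed places with every probe counted (1766 and 1928, 1181 and 1247), with median scaling for miR-3118-3p (1102 and 1167), with array weights for miR-4307-3p and the difference, and without miR-3118-3p pull-down replicate 1 for the difference. The input count was 0 in every setting.

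Lists called (10, 9, 0 and 1 in the order of the comparisons) ranged without single arrays from 7 to 10, 5 to 11, 0 to 2 and 0 to 2. An estimated correlation left 0, 1 and, for the inputs, 0. Cyclic loess left 5 with miR-4307-3p; for the inputs, averaging probes gave 2 and the minimum mean 0. With the replicate number as a block, lists were 1 for the difference and 2 for the inputs. That block called 2492, 1480 and 809 genes, of which 2219, 1318 and 712 were among the 2258, 1355 and 727 without it. For miR-3118-3p the numbers were not shown to pair arrays (0.344, 0.0736 and 0.476, not all over 0.1), though every pull-down correlated best with its own number. Between the 2 microRNAs they were not shown to pair arrays either, at 0.295, 0.125 and -0.217 for the pull-downs and 0.017, -0.050 and -0.289 for the inputs. The block ended the call of TGF-beta, Wnt and Notch signalling with miR-3118-3p (adjusted p = 0.0598) and called MCCC1 for the difference (0.0234), carboxylases with miR-4307-3p (0.0388), mitochondrial ribosomal proteins for the difference (0.0451) and G2/M and mitosis between inputs (0.0499). With the preset correlation it changed no other call of a named gene or list. With the block and an estimated correlation 0 lists were called in every comparison, so oxidative phosphorylation with miR-4307-3p lost its call (0.148).

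Of 1788 values of named genes without single arrays, 1701 kept direction and side of the threshold, 57 lost the threshold, 6 gained it and 24 reversed; in the other settings these were 1436, 19, 6 and 12 of 1473. Leaving out an array that is not in a comparison cannot change its log2 value, so many of the 1788 values could not reverse. Most named genes were also chosen as called genes, so these shares do not describe all genes. The only called gene that reversed was SNHG7 with miR-4307-3p, at 0.19 with probes averaged, since another of its probes gave 1.22. All others had not passed the test. With probes averaged, ACTB gave -0.066 and -0.25 with the microRNAs and GAPDH -0.077 between inputs. With array weights, HLCS gave -0.014, MCCC1 0.012 and PCCA 0.11 with miR-3118-3p, ACACB -0.068 for the difference and GAPDH -0.038 between inputs. ACACB for the difference was -0.0051 after quantile normalization and -0.23 between pull-downs, and GAPDH between inputs -0.00417 after median scaling. Values that changed sign without single arrays ranged, with miR-3118-3p, from -0.077 to 0.31 for HLCS, -0.16 to 0.074 for MCCC1, -0.015 to 0.11 for PC and -0.11 to 0.052 for PCCA. With miR-4307-3p they ranged from -0.063 to 0.15 for ACTB and -0.018 to 0.17 for PCCA. For the difference they ranged from -0.034 to 0.31 for ACACA, -0.095 to 0.13 for ACACB, -0.054 to 0.22 for GAPDH, -0.30 to 0.081 for HLCS, -0.19 to 0.0067 for PCCA and -0.065 to 0.33 for PCCB. Between inputs they ranged from -0.081 to 0.0076 for ACTB and -0.037 to 0.062 for GAPDH.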

Other observations

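The test of input levels was chosen after the near-zero input difference of the miR-4307-3p genes had been seen. The tests on gene size and signal level, and the counts of splits, were set before their results, apart from the estimated correlation required for gene size.

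Some mRNAs of very large proteins were higher in both pull-downs, in which 33 and 35 of 72 oxidative phosphorylation mRNAs were lower and 6 and 2 higher (adjusted p = 0.0645 and 0.0284 for the list with an estimated correlation, and 0.118 and 0.148 with the replicate number as a block as well). Of 86 very large proteins other than those that prompted the list, 16 were higher and 2 lower with miR-3118-3p and 15 and 0 with miR-4307-3p, with medians of 0.17 and 0.15. The higher of the camera p-values was 0.00197, which met the criterion set before. With an estimated correlation, required only after the p-values were seen, they were 0.301 and 0.162, so length-dependent recovery apart from the microRNA cannot be told apart from chance here. The signal level of the genes is argued against for oxidative phosphorylation, whose medians of -0.35 and -0.41 lay at percentile 0 among 10000 random lists matched on signal.

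Repression of mRNA levels would lower a recovered mRNA in the cells given its microRNA. The 103 genes higher by at least 1 in the miR-3118-3p pull-down than in the other had a median of 0.070 between inputs (miR-3118-3p minus miR-4307-3p), and the 273 genes higher in the miR-4307-3p pull-down had -0.02. Neither median lay in the direction of repression. However, the genes were chosen on the pull-downs without correction for input. That choice favours genes with a higher input of the same microRNA, the direction found, so the signs do not count against repression. Camera gave p = 0.000928 and p = 0.425, but p = 0.271 and p = 0.791 with an estimated correlation, so the test with its larger median of 0.070 decides nothing.

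For 3 against 3 arrays the 10 splits are too few to give a share under 0.05. They exchanged arrays freely and did not keep to the pairs that the replicate numbers give for miR-4307-3p. The real split of the miR-3118-3p arrays called 2258 genes and the highest other 0, and that of the miR-4307-3p arrays 1355 and 0, in each case 1 split of 10. For the inputs all 10 of 10 splits gave as many as the real 0, which was fixed in advance and tests nothing. Every other split of a pull-down and its input mixes the 2 kinds of array. Part of the real difference then stays in the contrast and the rest enters the spread. Calls of 0 genes were thus likely in advance, and list calls in those splits may reflect the real difference. For the pull-downs these counts therefore do not measure chance. As many lists were called in 3 of 10 splits with miR-3118-3p (10 real, 12 highest other), 1 of 10 with miR-4307-3p (9 and 8) and 7 of 10 for the inputs (1 and 12). The counts of members stand first in the account of each list. They are to be read against the shares over all genes: 12.7% higher and 10.9% lower with miR-3118-3p, and 8.04% and 6.11% with miR-4307-3p. With miR-4307-3p, the 5 of 50 E3 ligases higher and the 2 of 21 glycolysis genes lower lie near these shares.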
